A study of Homo sapiens with 28 samples.

How the data were processed

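Total RNA was sequenced from LNCaP cells, an established human prostate cancer line. The 28 libraries fell into 7 groups of 4 by their labels. In 5 of the groups the cells received tunicamycin (2.5 µg/mL, 18 h) together with the PERK inhibitor or an siRNA against PERK or ATF4, and the other two groups, both with a control siRNA, received tunicamycin or the solvent DMSO alone. Tunicamycin blocks the first step of N-glycosylation and so loads the endoplasmic reticulum (ER) with unfolded protein. PERK, encoded by EIF2AK3, is an ER stress sensor kinase, and ATF4 is a transcription factor made when PERK and related kinases phosphorylate eIF2α. Treatment began 2 days after siRNA transfection. The inhibitor, GSK2606414, was used at 100 nM. The series' design text describes separate experiments for the 4 samples of a group, so the replicate spread covers repeated cultures of 1 cell line.

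The values were raw counts of reads per gene, which the authors deposited in 6 tables of 25370 lines each. Per the submitters' processing notes, the tools named were TopHat2 2.1.0, featureCounts 1.5.0-p1 and DESeq2 1.10.1, with genome build hg19; their settings and the gene annotation are not given in the sources used here. Per the labels' protocols, libraries were made with a strand-specific kit. Whether counting used the strand is not given, so genes that overlap another gene, and members of near-identical families, are uncertain. By the exon models in the deposited tables, the genes named here that overlap another gene are ATF5, COLCA1, DDIT3, DERL3, DNAJB9, DTL, EIF2AK3, ENTPD3, ERICH2, FTH1, HSP90B1, KLHL1, PDSS1, RAD54L, SEMA6A, SHMT1, SLC6A9, SLC7A11, SQSTM1, STARD4, SYP, TM4SF1, TMEM97, TMEM9B, TNFRSF10B and TYMS. Uncertain for other reasons are the families of UGT2B10 and UGT2B11, AKR1C1 and AKR1C2, the pseudogenes ZSCAN12P1 and ROCK1P1, and TARP within the T cell receptor gamma locus. The TM siCtrl columns recurred in the tables with 0 differing values and were used once. A single line without a gene name held 0 counts and was left out, leaving 25369 genes. The tables held 0 genes of the mitochondrial chromosome, so the share of mitochondrial reads was not analysed here.

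Counts were summed by library, scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group with a minimum count of 10 and a minimum total of 15, group means model, robust quasi-likelihood F-test, two-sided). This left 14314 genes. All 28 libraries entered 1 fit, so that all groups shared 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, separately for each of 10 comparisons, and a gene was called at an adjusted p under 0.05. Each adjusted p of a gene below comes from this edgeR fit unless another tool is named. Fold changes are log2 values with an approximate standard error (SE), the absolute log2 change divided by the square root of the F statistic. Levels are TMM-scaled CPM with SD, n = 4. For a gene with 0 counts in all libraries of a group, the fold was bounded against 3 counts summed over that group, which covers counting error only.

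The named genes followed a rule set before the data were examined: the targeted genes and FAM129A in every group, the 10 most raised and 10 most lowered genes with tunicamycin, 8 and 8 for the inhibitor and for both siRNAs of a target (ranked by the smaller of the oligo effects), 3 and 3 for direct comparisons, and up to 4 called members per gene list. Genes of the ranked sets needed a mean log2 CPM of at least 1, no overlap between the groups' values and a standard gene symbol. Some list members named outside this rule were chosen after their values were seen. These are KLK2 with the inhibitor, STEAP2 and EIF2AK4 with tunicamycin, SC5D with the PERK siRNAs and PDIA4 with the ATF4 siRNAs, and ATF5, DDIT4, DNAJC3, FTH1, HMGCS1, HMOX1 and HYOU1 where the rule named them only in another comparison. Some genes that the rule or the lists named are not reported here. Gene lists were likewise fixed before the data were examined, from textbook knowledge. Of 25 lists, 23 had at least 3 tested members. The lists of mitochondrially encoded genes (0 members in the tables) and leukocyte markers (2 members tested) could not be tested. Lists were tested with camera in limma 3.58.1 (voom weights, preset inter-gene correlation 0.01), adjusted over the 138 tests of 23 lists in 6 comparisons against a control group, and called at an adjusted p under 0.05. The same test with an estimated correlation and fry stand beside it. Camera compares a list with the other genes. Fry asks whether the genes of a list move on balance one way, and its mixed p whether they change in either direction, with no comparison to other genes. Of the 138 tests, 88 were called, and 10 of these held with an estimated correlation. Tests of the lists in the 4 direct comparisons (92 tests, adjusted together) and the overlap of inhibitor and PERK siRNA effects were chosen after the data were examined.

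Comparisons against the same TM siCtrl libraries share their chance values. Unchanged groups were therefore simulated 20 times against shared controls, and overlaps and correlations were recomputed with the 4 TM siCtrl libraries divided into 2 pairs. The oligos of a target were given different pairs when compared with each other, but shared a pair when set together against the tunicamycin or inhibitor effect, which had the other pair. The overlap of independent lists was computed for each direction as the product of both call counts over the genes tested.

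Alternatives were the DESeq2 test (1.42.0), limma-voom, DESeq2 size factors, upper-quartile factors, no low-count filter, a stricter filter (1 CPM in 4 libraries), the replicate number as a block, only the compared groups in the fit, each library left out in turn and a minimum fold change of 2. Other splits of the same libraries were tested for every comparison, 35 splits for 4 against 4 libraries and 100 drawn splits for the larger sets. The test was tried on simulated counts of 13996 genes, of which 200 were changed. For the tunicamycin comparison it recovered 55.2% of genes changed 1.25-fold, 82.1% of those changed 1.5-fold and 93.9% of those changed 2-fold, and 2.87% of calls were unchanged genes. For the inhibitor, siPERK-1, siPERK-3, siATF4-2 and siATF4-3 comparisons these values were 47.8% to 52.2%, 73.1% to 86.6%, 86.4% to 92.4% and 2.56% to 4.97%. Replicates of every group differed by more than sampling noise (chi-square per gene 1.79 to 9.28 over 42 pairs), so each library counted once. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.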

Results

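Raw counts were analysed for 25369 genes in 28 libraries of LNCaP prostate cancer cells, with 4 libraries in each of 7 groups. Cells transfected with a control siRNA received the solvent (DMSO siCtrl) or tunicamycin (TM siCtrl), a block of N-glycosylation that causes ER stress. The other 5 groups received tunicamycin with the PERK inhibitor (TM PERKi siCtrl), with either siRNA against PERK (TM siPERK-1, TM siPERK-3) or with either siRNA against ATF4 (TM siATF4-2, TM siATF4-3). Library totals were 15105353 to 17221117 counts in DMSO siCtrl, 14052883 to 17253801 in TM siCtrl, 11580800 to 15593975 in TM PERKi siCtrl, 13253835 to 16789370 in TM siPERK-1, 12251524 to 12606231 in TM siPERK-3, 12014347 to 13608748 in TM siATF4-2 and 10794637 to 13664563 in TM siATF4-3. The 10 most abundant genes took 5.05% to 9.85% of a library. Of the genes, 14314 had enough counts to be tested. Fold changes are given as log2 values ± SE and levels as mean CPM ± SD, with n = 4 libraries per group throughout.

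The targeted genes followed the labels. EIF2AK3, the gene of PERK (hg19 chromosome 2, 88856259 to 88927094, minus strand), stood at 30.2 ± 0.742 CPM in DMSO siCtrl and 89.2 ± 6.51 CPM in TM siCtrl. Its level was 24.6 ± 4.0 CPM with siPERK-1 and 21.5 ± 2.14 CPM with siPERK-3. Against TM siCtrl these were log2 changes of −1.86 ± 0.07 (adjusted p = 2.99e-22) and −2.05 ± 0.07 (adjusted p = 3.14e-23). With the inhibitor, which acts on the kinase and not on its transcript, EIF2AK3 was higher at 125.1 ± 4.25 CPM (0.49 ± 0.06). It stood at 100.3 ± 6.45 CPM with siATF4-2 and 80.9 ± 1.88 CPM with siATF4-3. ATF4 (chromosome 22, 39916564 to 39918691) rose from 605 ± 85.3 to 1511 ± 37.4 CPM with tunicamycin (1.32 ± 0.15). It fell to 237 ± 82.4 CPM with siATF4-2 (−2.67 ± 0.16) and 114 ± 19 CPM with siATF4-3 (−3.73 ± 0.17), a difference between the oligos of 1.06 ± 0.16 (adjusted p = 6.10e-05). Its level was 1415 ± 61.2 CPM with the inhibitor, 1415 ± 40.4 CPM with siPERK-1 and 1158 ± 42.7 CPM with siPERK-3. None of these differences from TM siCtrl passed the test in edgeR (−0.09 ± 0.15, −0.10 ± 0.15 and −0.38 ± 0.15).

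FAM129A, a stress-induced gene also known as NIBAN1, whose product affects the phosphorylation of translation factors (chromosome 1, 184760159 to 184943718), rose from 18.8 ± 2.96 to 187 ± 11.1 CPM with tunicamycin (3.31 ± 0.19). Both PERK siRNAs lowered it, to 127 ± 14.6 CPM (−0.56 ± 0.16) and 118 ± 19.3 CPM (−0.67 ± 0.17), and so did siATF4-2 with 55.3 ± 16.1 CPM (−1.76 ± 0.18) and siATF4-3 with 14.6 ± 5.61 CPM (−3.67 ± 0.21). With the inhibitor it stood at 247 ± 12.1 CPM, a difference of 0.40 ± 0.16 that did not pass the edgeR test (adjusted p = 0.0570, and 4.71e-07 to 0.120 over its alternatives, with calls in limma-voom, with the replicate number as a block and when only the compared groups were fitted). The same settings called ATF4 lower with siPERK-3 (adjusted p = 0.0554 against 1.75e-07 to 0.116 over its alternatives). With the inhibitor ATF4 was called lower when only the compared groups were fitted (−0.10, adjusted p = 0.0489, the lowest of a range up to 0.779 over its alternatives). The fall of FAM129A with siPERK-1 was not called without TM siPERK-1 replicate 4 (−0.49, adjusted p = 0.0520, the highest of its alternatives, which began at 9.59e-06). EIF2AK3 with siATF4-2 (0.17 ± 0.06, adjusted p = 0.0227) was not called with upper-quartile factors (0.13, adjusted p = 0.0773) or without TM siCtrl replicate 1 (0.12, adjusted p = 0.131). Nor was it without TM siATF4-2 replicate 2 (0.13, adjusted p = 0.0981), with a range of 0.00450 to 0.131 over its alternatives. With siATF4-3 EIF2AK3 was not called (−0.14 ± 0.06, adjusted p = 0.0586), but it was with upper-quartile factors (−0.17, adjusted p = 0.0218), when only the compared groups were fitted (−0.15, adjusted p = 0.0203) and without TM siCtrl replicate 1 (−0.19, adjusted p = 0.0139), within a range of 0.0139 to 0.188 over its alternatives.

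**Figure D1:**
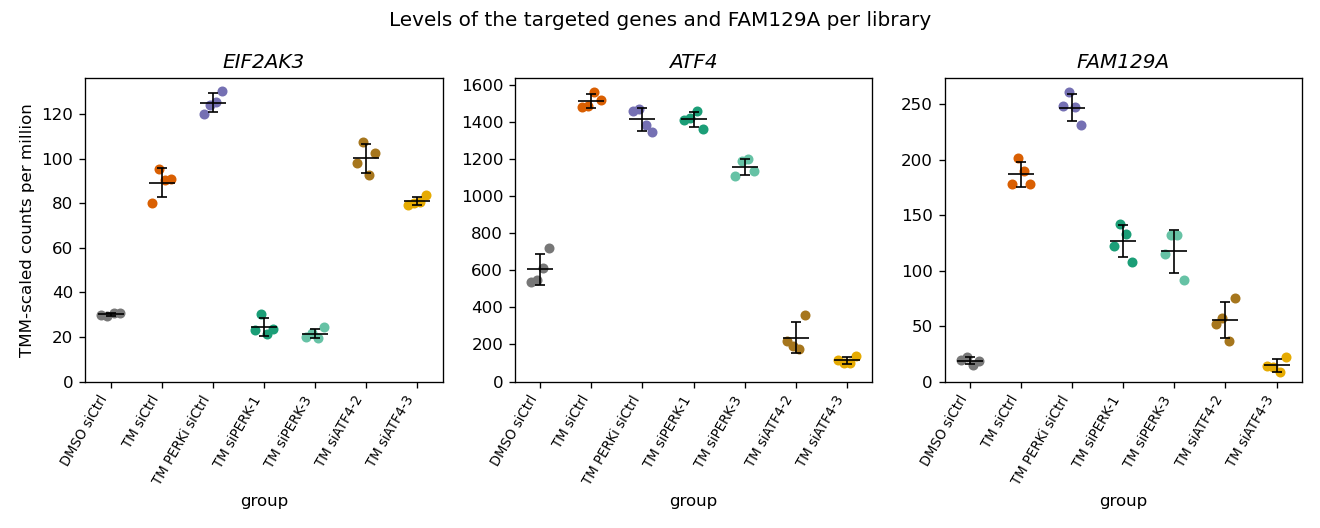
TMM-scaled CPM of EIF2AK3, ATF4 and FAM129A in each library (points), with the mean and SD of the 4 libraries of each group (black bars). EIF2AK3 was lowest in the groups with an siRNA against PERK (24.6 and 21.5 CPM), ATF4 in those with an siRNA against ATF4 (237 and 114 CPM).

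The response to tunicamycin was measured in cells with the control siRNA. Tunicamycin raised ER chaperones, genes of ER-associated degradation and secretory pathway genes in nearly complete sets, raised targets of ATF4 and CHOP, and lowered cell cycle genes and androgen-regulated genes. With an estimated correlation the list calls of the ATF4 and CHOP targets (adjusted p = 0.0577) and of androgen-regulated genes (adjusted p = 0.159) did not hold. HSPA5, the main ER chaperone, rose by 3.77 ± 0.10, DNAJB9 by 3.37 ± 0.07 and HSP90B1 by 3.16 ± 0.06, while DDIT3, the gene of the stress-induced transcription factor CHOP, rose by 3.79 ± 0.17. Kallikrein genes KLK2 (−2.74 ± 0.14) and KLK3 (−2.61 ± 0.25, the gene of prostate-specific antigen) fell. In all, 4909 genes were higher and 4974 lower, together 69.0% of those tested, with 1215 and 1041 of them changed at least 2-fold.

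Among called genes with a mean log2 CPM of at least 1 and a standard symbol, the most raised were LCN2, which encodes a secreted iron-siderophore carrier (7.79 ± 0.38, adjusted p = 8.60e-16), FIBIN (7.30 ± 0.47), the collagen gene COL16A1 (6.28 ± 0.39), the receptor gene GPR1 (5.41 ± 0.23) and ERICH2 (5.12 ± 0.27). They were followed by the lysosomal membrane gene LAMP3 (5.03 ± 0.25), the protein disulfide isomerase gene AGR2 (4.75 ± 0.29), the xanthine dehydrogenase gene XDH (4.70 ± 0.16), the protease inhibitor gene SERPINA3 (4.69 ± 0.24) and ENTPD3 (4.55 ± 0.16). The most lowered of this set were the prostate-enriched receptor gene OR51E1 (−3.96 ± 0.26, adjusted p = 2.68e-14), FAM111B (−3.70 ± 0.25), DTL (−3.58 ± 0.17) and the replication factor gene MCM10 (−3.53 ± 0.19). Next came the replicative helicase genes MCM2 (−3.51 ± 0.19) and MCM5 (−3.23 ± 0.19), the DNA methylation cofactor gene UHRF1 (−3.47 ± 0.15), HELLS (−3.32 ± 0.14), the recombination gene RAD54L (−3.17 ± 0.13) and TARP (−3.12 ± 0.17). LCN2 and FIBIN had at most 4 counts in any DMSO library, so the size of their change is imprecise, and without DMSO siCtrl replicate 2 the value of LCN2 was 8.53.

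All 26 ER chaperones and folding enzymes rose (26 also when adjusted over the list alone), with a median log2 change of 1.90 (camera adjusted p = 3.91e-22, and adjusted p = 0.0280 with an estimated correlation). They included CRELD2 (3.09 ± 0.06) and HYOU1 (2.88 ± 0.05). All 34 secretory pathway targets of XBP1 rose as well (34 adjusted over the list alone). The median was 1.49 (camera adjusted p = 2.32e-24, adjusted p = 0.0280 with an estimated correlation). Among them were WIPI1 of autophagosome formation (2.74 ± 0.07), the coat protein gene SEC24D (2.41 ± 0.06) and TRAM1 (2.37 ± 0.05). Of 22 genes of ER-associated degradation, 19 rose (19 adjusted over the list alone) and 0 fell (median 1.45, camera adjusted p = 3.34e-12, adjusted p = 0.0202 with an estimated correlation). HERPUD1 rose by 3.14 ± 0.07, VIMP by 2.63 ± 0.06 and the ubiquitin ligase subunit gene SEL1L by 2.51 ± 0.09. Among 35 N-glycosylation enzymes 25 rose and 4 fell (25 and 4 adjusted over the list alone). Their median was 0.90 (camera adjusted p = 1.25e-07, adjusted p = 0.0492 with an estimated correlation). These included GFPT1, which starts hexosamine synthesis (2.63 ± 0.09), and the oligosaccharyltransferase subunit gene MAGT1 (1.86 ± 0.05).

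ATF4-CHOP stress targets rose in 28 of 29 cases (28 adjusted over the list alone). The median was 1.63 (camera adjusted p = 3.36e-12, adjusted p = 0.0577 with an estimated correlation). The transcription factor gene ATF3 rose by 3.06 ± 0.16 and DNAJC3, which encodes an inhibitor of PERK, by 2.48 ± 0.06. Amino acid transporters moved the same way in 13 of 17 cases, with 2 lower (13 and 2 adjusted over the list alone). Their median was 1.09 (camera adjusted p = 7.59e-05, adjusted p = 0.0817 with an estimated correlation). Among them were SLC3A2, the shared heavy chain of such transporters (3.42 ± 0.10), the glycine transporter gene SLC6A9 (2.79 ± 0.16) and the cystine transporter gene SLC7A11 (2.57 ± 0.19). Of 20 amino acid synthesis and one-carbon enzymes 16 rose and 3 fell, the same numbers as when adjusted over the list alone (median 0.63, camera adjusted p = 0.00123, adjusted p = 0.252 with an estimated correlation). Mitochondrial ALDH1L2 rose (1.65 ± 0.15) and cytosolic SHMT1 fell (−1.73 ± 0.08). Cytosolic aminoacyl-tRNA synthetases were higher in 12 and lower in 5 of 20 cases (12 and 5 adjusted over the list alone). The median was 0.56 (camera adjusted p = 0.00741, adjusted p = 0.241 with an estimated correlation). NRF2 targets rose in 14 of 19 and fell in 1 (14 and 1 adjusted over the list alone). Their median was 1.35 (camera adjusted p = 5.34e-05, adjusted p = 0.184 with an estimated correlation). They included the ferritin gene FTH1 (1.76 ± 0.10) and the heme oxygenase gene HMOX1 (1.64 ± 0.13). Autophagy and lysosome genes rose in 17 and fell in 3 of 23 cases (18 and 3 adjusted over the list alone). The median was 0.22 (camera adjusted p = 0.00124, adjusted p = 0.0577 with an estimated correlation). They included MAP1LC3B (2.54 ± 0.12) and the autophagy receptor gene SQSTM1 (1.35 ± 0.06).

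All 32 cell cycle genes fell with tunicamycin (32 adjusted over the list alone). Their median was −1.74 (camera adjusted p = 9.62e-19, adjusted p = 0.0202 with an estimated correlation). The helicase gene MCM4 (−2.98 ± 0.14) and the cell cycle regulator gene E2F1 (−2.77 ± 0.13) were among them. Androgen-regulated genes fell in 20 of 22 cases and rose in 1 (20 and 1 adjusted over the list alone). The median was −1.11 (camera adjusted p = 1.25e-07, adjusted p = 0.159 with an estimated correlation). The metalloreductase gene STEAP4 (−2.74 ± 0.25) fell, and STEAP2 rose (0.34 ± 0.05). Cytosolic heat shock genes were lower in 14 and higher in 3 of 19 cases (14 and 3 adjusted over the list alone). Their median was −0.63 (camera adjusted p = 0.00143, adjusted p = 0.349 with an estimated correlation). HSPH1 (−1.55 ± 0.16) and the inducible HSP90 gene HSP90AA1 (−1.36 ± 0.08) fell. Fatty acid synthesis genes fell in 11 and rose in 3 of 15 cases (11 and 3 adjusted over the list alone). The median was −0.60 (camera adjusted p = 0.0223, adjusted p = 0.456 with an estimated correlation). The fatty acid synthase gene FASN fell (−2.33 ± 0.14). Ribosomal protein genes were raised by small amounts in 26 of 50 cases and lowered in 2 (25 and 2 adjusted over the list alone). Their median was 0.11 (camera adjusted p = 0.0190, adjusted p = 0.575 with an estimated correlation).

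The remaining lists did not pass camera with tunicamycin although single members changed. Cholesterol synthesis genes were higher in 5 and lower in 10 of 24 cases (3 and 10 adjusted over the list alone; camera adjusted p = 0.293), with SC5D at 1.78 ± 0.05 and TMEM97 at −1.31 ± 0.06. For p53 targets the counts were 13 and 5 of 23 (14 and 5 adjusted over the list alone; camera adjusted p = 0.0913), with GADD45A at 1.73 ± 0.11 and DDB2 at −1.27 ± 0.08. Interferon-stimulated genes were higher in 6 and lower in 7 of 24 (6 and 6 adjusted over the list alone), with ISG20 at 2.18 ± 0.09 and OAS3 at −1.89 ± 0.13, a median of 0.01, a mean of −0.01 and an upward camera direction (adjusted p = 0.971). NF-kB targets were lower in 7 and higher in 0 of 10 (7 and 0 adjusted over the list alone; camera adjusted p = 0.116), with TNFAIP2 at −2.06 ± 0.32. Unfolded protein sensors and eIF2 kinases were higher in 11 and lower in 7 of 18 (11 and 7 adjusted over the list alone; camera adjusted p = 0.0735), with the sensor genes ERN1 at 1.75 ± 0.08 and ATF6 at 1.49 ± 0.05 and the kinase gene EIF2AK4 at −0.98 ± 0.05. Neuroendocrine markers (camera adjusted p = 0.287, 2 higher and 4 lower of 8, the same adjusted over the list alone) included SYT4 (−2.47 ± 0.20) and TUBB3 (1.54 ± 0.15). Markers of other cell types did not pass either: basal epithelial markers had 2 higher and 1 lower of 4 (camera adjusted p = 0.364, the same counts adjusted over the list alone), and fibroblast and mesenchymal markers 4 and 2 of 7 (the same adjusted over the list alone; median 0.46, camera upward with adjusted p = 0.737, fry downward with adjusted p = 0.595). Fry was called for each list that camera called in this and the following comparisons against a control.

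The PERK inhibitor during tunicamycin raised 18 of 26 ER chaperone genes and 16 of 24 cholesterol synthesis genes and lowered 15 of 22 androgen-regulated genes. With an estimated correlation these list calls did not hold (adjusted p = 0.0556, adjusted p = 0.175 and adjusted p = 0.213). PDIA4, a protein disulfide isomerase gene, rose by 1.74 ± 0.07 (from 1596 ± 236 to 5327 ± 461 CPM), DERL3 of ER-associated degradation by 2.08 ± 0.14 and HSPA5 by 1.13 ± 0.09, while KLK3 fell from 431.5 ± 44.2 to 64.5 ± 30.7 CPM (−2.74 ± 0.27). DDIT3 and ATF3, targets of the pathway below PERK, were higher with the inhibitor by 1.31 ± 0.14 and 1.36 ± 0.14. Of the genes tested, 2601 were higher and 2511 lower (35.7%), and 114 and 111 of them changed at least 2-fold.

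The named raised genes were ZSCAN12P1 (2.35 ± 0.23, adjusted p = 3.03e-10), XDH (from 15.4 ± 0.61 to 65.9 ± 3.57 CPM), DERL3, MTUS2 (1.89 ± 0.15), the angiotensinogen gene AGT (1.87 ± 0.32), PDIA4, ROCK1P1 (1.61 ± 0.16) and the phospholipase gene PLCG2 (2.27 ± 0.59). A single library set the value of PLCG2: its counts were 551 in TM PERKi siCtrl replicate 3 and 38 to 53 in the other libraries of that group. Without that library the change was 0.53 (adjusted p = 0.0605), and over its alternatives the adjusted p ranged from 0.000819 to 0.149. The named lowered genes were KLK3, the xenobiotic-metabolism gene CYP1A1 (−2.66 ± 0.42, adjusted p = 1.71e-05), TM4SF1 (−1.70 ± 0.26), the adhesion molecule gene BCAM (−1.69 ± 0.22), the pro-apoptotic gene BMF (−1.68 ± 0.15), FAM65B (−1.62 ± 0.17), the triglyceride synthesis gene DGAT2 (−1.59 ± 0.26) and COLCA1 (−1.59 ± 0.37).

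ER chaperones rose in 18 of 26 cases with the inhibitor and fell in 1 (19 and 1 adjusted over the list alone). The median was 0.30 (camera adjusted p = 1.33e-15, adjusted p = 0.0556 with an estimated correlation). SDF2L1, a cofactor gene of HSPA5, rose by 1.18 ± 0.07. In ER-associated degradation 15 of 22 genes rose and 0 fell (16 and 0 adjusted over the list alone). Their median was 0.27 (camera adjusted p = 9.37e-13, adjusted p = 0.0202 with an estimated correlation). XBP1 secretory targets rose in 21 of 34 cases and fell in 0 (22 and 0 adjusted over the list alone). The median was 0.17 (camera adjusted p = 8.79e-09, adjusted p = 0.155 with an estimated correlation). Of the ATF4-CHOP stress targets 15 of 29 rose and 4 fell (17 and 4 adjusted over the list alone). Their median was 0.27 (camera adjusted p = 2.19e-04, adjusted p = 0.279 with an estimated correlation). The repressor gene NFIL3 (1.04 ± 0.10) rose, and the secreted stress cytokine gene GDF15 fell (−0.72 ± 0.13). Amino acid synthesis enzymes rose in 9 of 20 cases and fell in 0 (the same adjusted over the list alone). The median was 0.14 (camera adjusted p = 0.00110, adjusted p = 0.252 with an estimated correlation). Aminoacyl-tRNA synthetases rose in 7 and fell in 0 of 20 cases (the same adjusted over the list alone). Their median was 0.10 (camera adjusted p = 0.0185, adjusted p = 0.280 with an estimated correlation). Sensors and eIF2 kinases rose in 9 and fell in 4 of 18 cases (10 and 4 adjusted over the list alone). The median was 0.17 (camera adjusted p = 0.0136, adjusted p = 0.0817 with an estimated correlation). N-glycosylation enzymes rose in 12 and fell in 5 of 35 cases (13 and 6 adjusted over the list alone). Their median was 0.09 (camera adjusted p = 0.0386, adjusted p = 0.332 with an estimated correlation). The call ended without TM PERKi siCtrl replicate 2 (adjusted p = 0.0536), TM PERKi siCtrl replicate 3 (0.0659) or TM siCtrl replicate 4 (0.0664), with a range of 0.0159 to 0.0664.

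Androgen-regulated genes fell in 15 of 22 cases and rose in 2 with the inhibitor (15 and 2 adjusted over the list alone). The median was −0.39 (camera adjusted p = 2.84e-06, adjusted p = 0.213 with an estimated correlation). They included the TGF-beta regulator gene PMEPA1 (−1.13 ± 0.14) and KLK2 (−0.65 ± 0.15), while ACPP rose (1.08 ± 0.31). Cholesterol synthesis genes rose in 16 of 24 cases and fell in 1 (17 and 1 adjusted over the list alone). Their median was 0.42 (camera adjusted p = 9.36e-09, adjusted p = 0.175 with an estimated correlation). The sterol carrier gene STARD4 rose by 1.22 ± 0.08, and the sterol enzyme genes HSD17B7 and NSDHL by 0.98 ± 0.09 and 0.87 ± 0.06. Cell cycle genes rose in 16 and fell in 1 of 32 cases (17 and 1 adjusted over the list alone). The median was 0.25 (camera adjusted p = 1.02e-04, adjusted p = 0.206 with an estimated correlation). Heat shock genes rose in 11 and fell in 1 of 19 cases (the same adjusted over the list alone). Their median was 0.23 (camera adjusted p = 0.00148, adjusted p = 0.349 with an estimated correlation). P53 targets rose in 10 and fell in 2 of 23 cases (the same adjusted over the list alone). The median was 0.20 (camera adjusted p = 0.00776, adjusted p = 0.287 with an estimated correlation). TP53INP1, which promotes autophagy and cell death, fell (−0.98 ± 0.08). NF-kB targets rose in 5 and fell in 0 of 10 cases (6 and 0 adjusted over the list alone). Their median was 0.35 (camera adjusted p = 0.0227, adjusted p = 0.252 with an estimated correlation). The NF-kB subunit gene RELB (1.28 ± 0.31) and TNFAIP3 (1.19 ± 0.20) rose. Ribosomal protein genes were lower in 10 and higher in 0 of 50 cases (2 and 0 adjusted over the list alone). The median was −0.06 (camera adjusted p = 0.00420, adjusted p = 0.488 with an estimated correlation). NRF2 targets fell in 8 and rose in 2 of 19 cases (the same adjusted over the list alone). Their median was −0.08 (camera adjusted p = 0.0448, adjusted p = 0.456 with an estimated correlation). That call ended without TM siCtrl replicate 3 (adjusted p = 0.0553), TM siCtrl replicate 4 (0.0661) or TM PERKi siCtrl replicate 4 (0.0797), with a range of 0.0229 to 0.0797. Not called were amino acid transporters (camera adjusted p = 0.204), fatty acid synthesis (0.881), autophagy and lysosome (0.528), interferon-stimulated genes (0.971, camera downward and fry upward), neuroendocrine markers (0.971, camera upward with a median of −0.07), basal markers (0.114) and fibroblast markers (0.501).

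**Figure D2:**
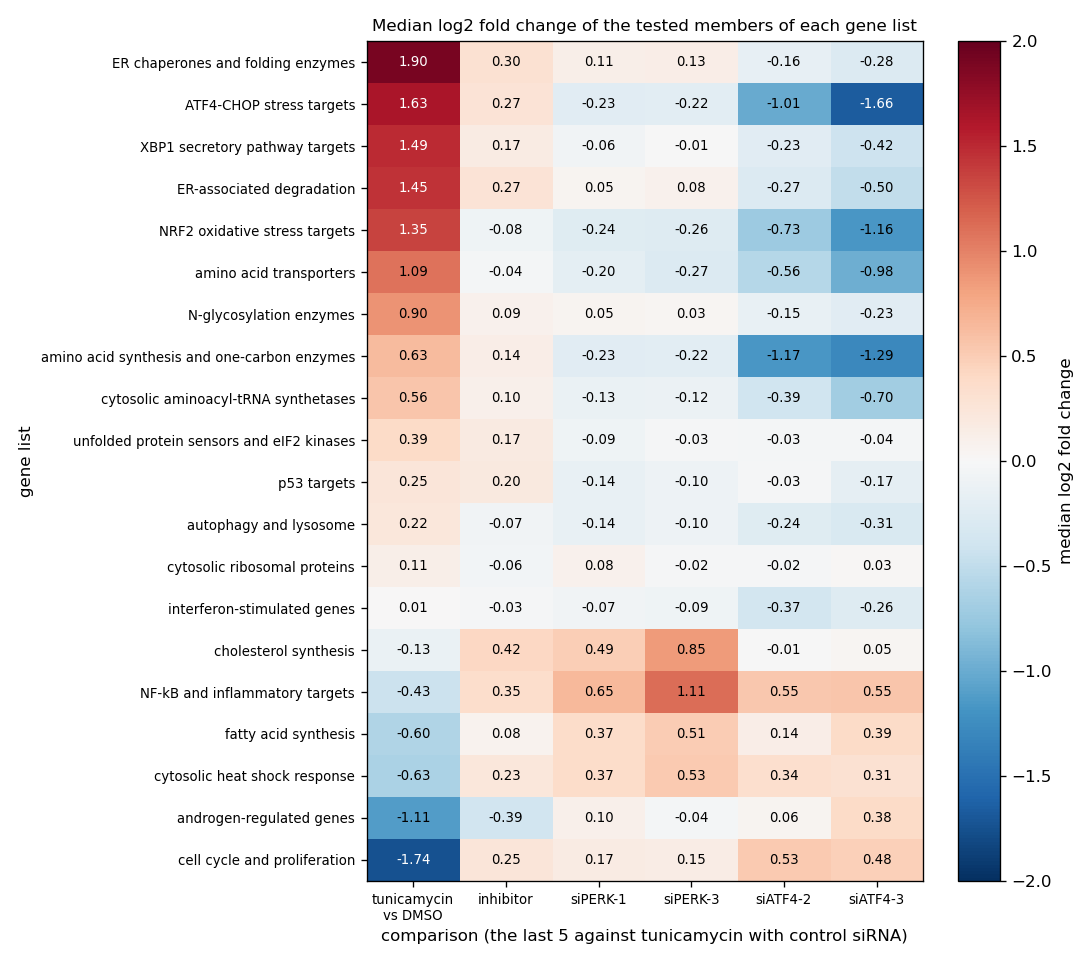
Median log2 fold change of the tested members of 20 gene lists (lines of the heatmap) in 6 comparisons (columns), with tunicamycin against DMSO first and the other 5 against tunicamycin with control siRNA. ATF4-CHOP stress targets stood at 1.63 with tunicamycin, 0.27 with the inhibitor, −0.23 and −0.22 with the PERK siRNAs and −1.01 and −1.66 with the ATF4 siRNAs.

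With siRNAs against PERK (values for siPERK-1 and then siPERK-3), 20 and 21 of 24 cholesterol synthesis genes, 11 and 11 of 15 fatty acid synthesis genes, 12 and 14 of 19 heat shock genes and 9 and 8 of 10 NF-kB targets rose, and 9 and 8 of 29 stress targets of ATF4 and CHOP fell. With an estimated correlation the calls held for NF-kB targets and for cholesterol synthesis with siPERK-3. They did not for cholesterol synthesis with siPERK-1 (adjusted p = 0.0577), fatty acid synthesis (adjusted p = 0.171 and 0.0577), heat shock genes (adjusted p = 0.184 and 0.0577) and the stress targets (adjusted p = 0.299 and 0.315). PDIA4 rose by 1.69 ± 0.07 and 1.66 ± 0.07, the fatty acid synthase gene FASN by 0.95 ± 0.13 and 1.52 ± 0.13, and TNFAIP3, an inhibitor gene of NF-kB signalling, by 1.33 ± 0.19 and 1.87 ± 0.19. LAMP3, among the genes most raised by tunicamycin, fell (−1.28 ± 0.16 and −2.01 ± 0.19). With siPERK-1 1872 genes were higher and 1910 lower (26.4%), with siPERK-3 1874 and 1959 (26.8%), and changes of at least 2-fold numbered 99 and 71 and 101 and 123.

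The named genes raised by both oligos were the relaxin gene RLN1 (2.19 ± 0.33 and 2.02 ± 0.35), TMEFF2 (1.89 ± 0.24 and 2.11 ± 0.24) and ZSCAN12P1 (1.86 ± 0.23 and 1.77 ± 0.24). Others were the prostatic acid phosphatase gene ACPP (2.09 ± 0.29 and 1.76 ± 0.30), PDIA4, DERL3 (1.61 ± 0.14 and 1.69 ± 0.14), the glucuronosyltransferase gene UGT2B10 (1.41 ± 0.32 and 1.70 ± 0.32) and FAM19A4 (1.63 ± 0.22 and 1.35 ± 0.24). After EIF2AK3, the genes lowered by both were ID1, an inhibitor of basic helix-loop-helix factors (−1.55 ± 0.28 and −1.68 ± 0.29), DMGDH (−1.62 ± 0.25 and −1.49 ± 0.26) and HOPX (−1.49 ± 0.15 and −1.72 ± 0.16). The Golgi membrane gene TMEM165 (−1.52 ± 0.13 and −1.43 ± 0.13), GPR1 (−1.42 ± 0.15 and −1.70 ± 0.16), LAMP3 and the netrin receptor gene UNC5B (−1.26 ± 0.16 and −1.66 ± 0.18) fell as well. The adjusted p of these genes lay at or below 0.00247, the value of UGT2B10 with siPERK-1. Both oligos raised 1171 genes and lowered 1268. Simulated unchanged groups, with few calls, gave 0 and 0 and cannot test shared controls. Independent lists would share 245 and 261. With a different pair of TM siCtrl libraries for each oligo the counts were 606 to 666 and 720 to 758. Across genes, which are not independent replicates, the fold changes of the oligos had r = 0.774 against a simulated mean of 0.471 and 0.528 to 0.559 with split controls. Their covariance was 0.0780, against a simulated 0.0118.

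Cholesterol synthesis genes rose in 20 and 21 of 24 cases with siPERK-1 and siPERK-3 (20 and 22 adjusted over the list alone) and fell in 1 with each, with medians of 0.49 and 0.85 (camera adjusted p = 4.90e-16 and 8.61e-30, adjusted p = 0.0577 and 0.0226 with an estimated correlation). They included HMGCS1 (0.65 ± 0.11 and 1.47 ± 0.11) and INSIG1 (0.90 ± 0.15 and 1.43 ± 0.15), and SC5D fell (−0.35 ± 0.05 and −0.36 ± 0.05). Fatty acid synthesis genes rose in 11 and 11 of 15 cases and fell in 1 with each (11 and 11 higher, 2 and 1 lower adjusted over the list alone). Medians were 0.37 and 0.51 (camera adjusted p = 2.07e-06 and 1.10e-11, adjusted p = 0.171 and 0.0577 with an estimated correlation). The lipid phosphatase gene LPIN1 rose by 0.75 ± 0.10 and 1.43 ± 0.10. NF-kB targets rose in 9 and 8 of 10 cases with 0 lower (10 and 9 higher adjusted over the list alone). Their medians were 0.65 and 1.11 (camera adjusted p = 1.88e-06 and 1.10e-08, adjusted p = 0.0461 and 0.0209 with an estimated correlation). RELB rose by 1.44 ± 0.30 and 2.01 ± 0.29. Heat shock genes rose in 12 and 14 of 19 cases and fell in 1 with each (14 and 14 higher adjusted over the list alone). The medians were 0.37 and 0.53 (camera adjusted p = 6.68e-07 and 3.90e-13, adjusted p = 0.184 and 0.0577 with an estimated correlation). ER chaperones rose in 11 and 13 and fell in 4 and 6 of 26 cases (14 and 13 higher, 4 and 6 lower adjusted over the list alone). The list medians were 0.11 and 0.13 (camera adjusted p = 2.99e-06 and 2.86e-05, adjusted p = 0.216 and 0.252 with an estimated correlation). HSP90B1, the ER member of that family, rose by 0.87 ± 0.06 and 0.87 ± 0.06. Genes of ER-associated degradation rose in 8 and fell in 4 of 22 cases with each oligo (9 and 8 higher, 5 and 4 lower adjusted over the list alone; camera adjusted p = 0.0285 and 6.56e-04, adjusted p = 0.323 and 0.159 with an estimated correlation). Cell cycle genes rose in 11 and 8 and fell in 0 and 1 of 32 cases (the same adjusted over the list alone). Medians were 0.17 and 0.15 (camera adjusted p = 0.00109 and 0.00682, adjusted p = 0.261 and 0.334 with an estimated correlation). Neuroendocrine markers rose in 5 and 4 of 8 cases with 0 lower (the same adjusted over the list alone). Their medians were 0.70 and 0.64 (camera adjusted p = 5.57e-04 and 0.0114, adjusted p = 0.0544 and 0.117 with an estimated correlation).

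ATF4-CHOP stress targets fell in 9 and 8 of 29 cases with siPERK-1 and siPERK-3 and rose in 1 with each (11 and 9 lower adjusted over the list alone). The medians were −0.23 and −0.22 (camera adjusted p = 5.01e-04 and 8.13e-04, adjusted p = 0.299 and 0.315 with an estimated correlation). STC2 stood at −0.51 ± 0.14 and −0.69 ± 0.14, the death receptor gene TNFRSF10B at −0.61 ± 0.08 and −0.38 ± 0.08 and ATF5 at −0.39 ± 0.11 and −0.66 ± 0.11, while DNAJC3 rose (0.43 ± 0.05 and 0.44 ± 0.05). Amino acid synthesis enzymes fell in 8 and 11 of 20 cases and rose in 1 with each (10 and 12 lower adjusted over the list alone). The list medians were −0.23 and −0.22 (camera adjusted p = 0.00547 and 5.03e-04, adjusted p = 0.315 and 0.234 with an estimated correlation). Amino acid transporters fell in 8 and rose in 2 and 4 of 17 cases (8 and 10 lower, 3 and 4 higher adjusted over the list alone). Medians were −0.20 and −0.27 (camera adjusted p = 0.0299 and 0.00805, adjusted p = 0.312 and 0.241 with an estimated correlation). The neutral amino acid transporter gene SLC1A4 fell (−1.03 ± 0.09 and −1.17 ± 0.09). NRF2 targets fell in 11 and 10 of 19 cases and rose in 1 with each (11 and 12 lower adjusted over the list alone). Their medians were −0.24 and −0.26 (camera adjusted p = 6.56e-04 and 1.70e-05, adjusted p = 0.252 and 0.159 with an estimated correlation). HMOX1 fell (−0.51 ± 0.12 and −0.85 ± 0.12). Autophagy and lysosome genes fell in 11 and 9 and rose in 3 and 1 of 23 cases (13 and 10 lower adjusted over the list alone). The medians were −0.14 and −0.10 (camera adjusted p = 0.00110 and 9.59e-04, adjusted p = 0.0577 and 0.0577 with an estimated correlation). P53 targets fell in 7 and 6 of 23 cases and rose in 0 and 1 (7 and 6 lower adjusted over the list alone; camera adjusted p = 0.00508 and 0.0448, adjusted p = 0.268 and 0.396 with an estimated correlation). The siPERK-3 call ended without TM siCtrl replicate 1 (adjusted p = 0.0940) or TM siPERK-3 replicate 4 (0.180, over a range of 0.0150 to 0.180). Sensors and eIF2 kinases, a list that holds the target EIF2AK3, fell in 6 and 5 and rose in 1 and 2 of 18 cases (6 and 7 lower adjusted over the list alone; camera adjusted p = 0.00529 and 0.0429, adjusted p = 0.0577 and 0.159 with an estimated correlation). The sensor gene ERN1 fell (−0.62 ± 0.08 and −0.59 ± 0.08). The siPERK-3 call of that list ended without TM siCtrl replicate 2 (adjusted p = 0.0541), TM siCtrl replicate 3 (0.0510) or TM siPERK-3 replicate 2 (0.0775), over a range of 0.0189 to 0.0775.

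Lists called with siPERK-1 and not with siPERK-3 were aminoacyl-tRNA synthetases (camera adjusted p = 0.00403 and 0.117, adjusted p = 0.215 with an estimated correlation for siPERK-1, 9 and 7 of 20 lower and 1 and 3 higher, 11 and 10 lower and 2 and 4 higher adjusted over the list alone). So were ribosomal proteins (6.56e-06 and 0.270, adjusted p = 0.315 with an estimated correlation for siPERK-1, 19 and 5 of 50 higher and 0 and 8 lower, 20 and 5 higher and 0 and 8 lower adjusted over the list alone). Tested directly between the oligos, ribosomal proteins were higher with siPERK-1 (median 0.10, camera adjusted p = 9.30e-19, adjusted p = 0.0926 with an estimated correlation). Aminoacyl-tRNA synthetases were lower with siPERK-1 (median −0.05, camera adjusted p = 0.0329, adjusted p = 0.345 with an estimated correlation). Neither oligo gave a call for XBP1 secretory targets (camera adjusted p = 0.0913 and 0.608), N-glycosylation enzymes (0.273 and 0.0657), androgen-regulated genes (0.396 and 0.738), interferon-stimulated genes (0.288 and 0.421), basal markers (0.197 and 0.456) or fibroblast markers (0.182 and 0.858). With siPERK-3 the median and mean of 3 of these lists had opposite signs: androgen-regulated genes (−0.04 and 0.02, camera downward), basal markers (0.08 and −0.04, camera downward) and fibroblast markers (−0.00 and 0.05, camera upward). XBP1 targets were called lower with siPERK-1 without TM siCtrl replicate 1 (adjusted p = 0.0301), TM siPERK-1 replicate 2 (0.0420) or TM siPERK-1 replicate 3 (0.0454), over a range of 0.0301 to 0.192. N-glycosylation enzymes were called higher with siPERK-3 without TM siCtrl replicate 3 (0.0219) or TM siPERK-3 replicate 4 (0.0253), over a range of 0.0219 to 0.128.

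SiRNAs against ATF4 lowered stress targets, amino acid enzymes and transporters and NRF2 targets, and raised cell cycle genes (values for siATF4-2 and then siATF4-3). None of these list calls held with an estimated correlation: adjusted p = 0.0583 and 0.0544 for stress targets, 0.0678 and 0.0622 for enzymes, 0.0622 and 0.0622 for transporters, 0.0577 and 0.0577 for NRF2 targets, and 0.0621 and 0.141 for cell cycle genes. The asparagine synthetase gene ASNS (−1.95 ± 0.09 and −2.82 ± 0.09), the large neutral amino acid transporter gene SLC7A5 (−1.65 ± 0.14 and −3.54 ± 0.17) and CHAC1, which encodes a glutathione-degrading enzyme (−3.72 ± 0.28 and −5.81 ± 0.36), fell. The helicase gene MCM2 rose by 1.51 ± 0.20 and 1.37 ± 0.20. With siATF4-2 4061 genes were higher and 3899 lower (55.6%), of which 235 and 642 changed at least 2-fold, and with siATF4-3 4461 and 4401 (61.9%), of which 403 and 947 did.

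The named genes lowered by both oligos were the calcium-binding protein gene S100P (−4.51 ± 0.21 and −5.05 ± 0.23), LAMP3 (−3.95 ± 0.24 and −4.55 ± 0.26), LCN2 (−3.91 ± 0.25 and −5.65 ± 0.32), CHAC1 and FLRT1 (−3.61 ± 0.20 and −4.60 ± 0.23). Others were FIBIN (−3.59 ± 0.32 and −6.29 ± 0.47), ERICH2 (−3.54 ± 0.24 and −4.83 ± 0.29) and GPR1 (−3.48 ± 0.20 and −5.41 ± 0.26). Raised by both were TMEFF2 (2.25 ± 0.24 and 2.82 ± 0.24), KLHL1 (2.25 ± 0.16 and 2.69 ± 0.16), JAKMIP1 (2.24 ± 0.17 and 2.12 ± 0.17) and the semaphorin gene SEMA6A (2.08 ± 0.14 and 2.13 ± 0.14). So were the desmosome gene PKP1 (2.02 ± 0.23 and 2.42 ± 0.22), ZNF385B (2.00 ± 0.17 and 2.19 ± 0.16), TLL1 (1.77 ± 0.24 and 2.05 ± 0.23) and PDSS1 of coenzyme Q synthesis (1.73 ± 0.14 and 1.98 ± 0.14). The adjusted p of these genes was at most 4.83e-07, the value of TLL1 with siATF4-2. TM siATF4-2 replicate 4 had more ATF4 (358 CPM) than the other libraries of its group (177 to 221 CPM), and without it the values with siATF4-2 were −5.44 for S100P, −4.60 for LCN2, −4.36 for CHAC1 and −4.37 for FIBIN. Without TM siATF4-3 replicate 4 those with siATF4-3 were −6.27 for LCN2 and −7.51 for FIBIN. FGF21 had 0 counts in all 4 libraries with siATF4-3 and 28 to 40 in TM siCtrl, and was at least 35.3-fold lower, against a floor of 3 counts over the group.

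Both ATF4 oligos raised 3598 genes and lowered 3482. Independent lists would share 1266 and 1199 (simulated groups, again no test, 0 and 0). With a different pair of TM siCtrl libraries for each oligo the counts were 2899 to 3015 and 2856 to 2922. The fold changes had r = 0.922 across genes against a simulated mean of 0.463 and 0.839 to 0.852 with split controls. Their covariance was 0.385, against a simulated 0.0117.

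ATF4-CHOP stress targets fell in 24 and 27 of 29 cases with siATF4-2 and siATF4-3 and rose in 2 with each (the same adjusted over the list alone). The list medians were −1.01 and −1.66, the latter unchanged with FGF21 at its bound (camera adjusted p = 4.97e-12 and 1.89e-14, adjusted p = 0.0583 and 0.0544 with an estimated correlation). SESN2 (−1.43 ± 0.14 and −2.75 ± 0.15) and DDIT4 (−2.25 ± 0.22 and −2.62 ± 0.22), both repressors of mTORC1 signalling, fell. Amino acid synthesis enzymes fell in 16 of 20 cases with each oligo and rose in 3 and 4 (the same adjusted over the list alone). Medians were −1.17 and −1.29 (camera adjusted p = 9.48e-08 and 4.61e-08, adjusted p = 0.0678 and 0.0622 with an estimated correlation). The mitochondrial carboxykinase gene PCK2 (−2.53 ± 0.17 and −3.54 ± 0.19) and PSAT1 of serine synthesis (−1.81 ± 0.10 and −2.52 ± 0.10) fell. Amino acid transporters fell in 11 of 17 cases with each and rose in 3 with each (11 and 11 lower, 4 and 3 higher adjusted over the list alone). Their medians were −0.56 and −0.98 (camera adjusted p = 2.28e-05 and 2.08e-05, adjusted p = 0.0622 and 0.0622 with an estimated correlation). SLC6A9 (−2.26 ± 0.16 and −3.81 ± 0.18) and SLC7A11 (−1.84 ± 0.19 and −3.15 ± 0.20) were among those that fell. Aminoacyl-tRNA synthetases fell in 12 and 13 and rose in 5 and 6 of 20 cases (the same adjusted over the list alone). The medians were −0.39 and −0.70 (camera adjusted p = 0.00444 and 3.70e-04, adjusted p = 0.216 and 0.129 with an estimated correlation). NRF2 targets fell in 18 of 19 cases with each oligo and rose in 1 (the same adjusted over the list alone). The list medians were −0.73 and −1.16 (camera adjusted p = 1.59e-09 and 8.10e-10, adjusted p = 0.0577 and 0.0577 with an estimated correlation). The aldo-keto reductase gene AKR1C2 (−2.96 ± 0.25 and −4.12 ± 0.30) and FTH1 (−1.23 ± 0.10 and −1.97 ± 0.10) fell. Autophagy and lysosome genes fell in 15 and 17 and rose in 2 and 4 of 23 cases (17 and 17 lower adjusted over the list alone). Medians were −0.24 and −0.31 (camera adjusted p = 3.70e-04 and 1.84e-04, adjusted p = 0.0544 and 0.0461 with an estimated correlation). MAP1LC3B fell (−1.61 ± 0.12 and −2.42 ± 0.12).

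Lists of ER genes were called lower as well with both ATF4 siRNAs. ER chaperones fell in 17 and 20 and rose in 3 and 2 of 26 cases (the same adjusted over the list alone). Their medians were −0.16 and −0.28 (camera adjusted p = 8.13e-04 and 6.56e-06, adjusted p = 0.334 and 0.234 with an estimated correlation). HSPA5 fell (−0.97 ± 0.09 and −1.33 ± 0.09), while PDIA4 rose (0.56 ± 0.07 and 0.46 ± 0.07). In ER-associated degradation 18 of 22 genes fell with each oligo and 3 and 2 rose (the same adjusted over the list alone). The medians were −0.27 and −0.50 (camera adjusted p = 3.38e-05 and 2.09e-07, adjusted p = 0.0817 and 0.0544 with an estimated correlation). XBP1 secretory targets fell in 26 and 30 and rose in 1 and 0 of 34 cases (the same adjusted over the list alone). The list medians were −0.23 and −0.42 (camera adjusted p = 1.52e-07 and 3.62e-11, adjusted p = 0.184 and 0.0925 with an estimated correlation). Cell cycle genes rose in 28 and 25 of 32 cases with 0 lower (29 and 26 adjusted over the list alone). Medians were 0.53 and 0.48 (camera adjusted p = 9.36e-09 and 4.27e-06, adjusted p = 0.0621 and 0.141 with an estimated correlation). The thymidylate synthase gene TYMS rose by 1.16 ± 0.09 and 1.21 ± 0.09. NF-kB targets rose in 6 of 10 cases with each oligo and 0 fell (the same adjusted over the list alone). Their medians were 0.55 and 0.55 (camera adjusted p = 0.0464 and 0.0386, adjusted p = 0.299 and 0.280 with an estimated correlation). The siATF4-2 call ended without TM siCtrl replicate 2 (adjusted p = 0.0530, over a range of 0.0327 to 0.0530).

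Between the ATF4 oligos calls differed for 3 more lists, which is not by itself a difference between them. N-glycosylation enzymes were called lower with siATF4-3 (22 lower and 8 higher of 35, the same adjusted over the list alone; camera adjusted p = 0.0145, adjusted p = 0.269 with an estimated correlation) and not with siATF4-2 (camera adjusted p = 0.0738). With siATF4-2 upper-quartile factors (0.0409) and leaving out TM siCtrl replicate 4 (0.0480) gave a call, over a range of 0.0409 to 0.136. Androgen-regulated genes rose in 14 and fell in 3 of 22 cases with siATF4-3 (the same adjusted over the list alone). The median was 0.38 (camera adjusted p = 0.00797, adjusted p = 0.427 with an estimated correlation). KLK2 rose by 1.11 ± 0.14. Androgen-regulated genes were not called with siATF4-2 (camera adjusted p = 0.506). Heat shock genes rose with siATF4-2 in 12 and fell in 4 of 19 cases (13 and 4 adjusted over the list alone; camera adjusted p = 0.0199, adjusted p = 0.475 with an estimated correlation). With siATF4-3 they missed the call (camera adjusted p = 0.0527), which came with upper-quartile factors (0.0464) and without TM siCtrl replicate 4 (0.0474), TM siATF4-3 replicate 2 (0.0462) or TM siATF4-3 replicate 3 (0.0479), over a range of 0.0462 to 0.0637. Between the oligos, N-glycosylation enzymes were higher with siATF4-2 (median 0.07, camera adjusted p = 0.00743, adjusted p = 0.222 with an estimated correlation). Heat shock genes were not called between them (camera adjusted p = 0.904). Not called with either were cholesterol synthesis (camera adjusted p = 0.738 and 0.744), fatty acid synthesis (0.745 and 0.162), p53 targets (0.418 and 0.0817), interferon-stimulated genes (0.115 and 0.313) and sensors and eIF2 kinases (0.396 and 0.288). The same held for ribosomal proteins (0.155 and 0.738, called lower with siATF4-2 under upper-quartile factors at 0.0301, over a range of 0.0301 to 0.279), neuroendocrine markers (0.684 and 0.418, with a median of −0.02 and a mean of 0.14 for siATF4-2), basal markers (0.114 and 0.257) and fibroblast markers (0.747 and 0.787).

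The inhibitor and the PERK siRNAs were then compared directly. Against the mean of the PERK siRNA groups, the inhibitor group had higher EIF2AK3 (2.44 ± 0.06), higher GCNT3, a gene of mucin glycosylation (2.32 ± 0.19) and higher PLCG2 (2.39 ± 0.50, 0.65 without TM PERKi siCtrl replicate 3). It had lower OR51E1 (−2.76 ± 0.34, −3.40 without TM PERKi siCtrl replicate 4), UGT2B11 (−2.31 ± 0.42) and TM4SF1 (−2.23 ± 0.23). ATF4-CHOP stress targets were higher with the inhibitor in 21 and lower in 2 of 29 cases (22 and 2 adjusted over the list alone). Their median was 0.53 (camera adjusted p = 2.02e-08, adjusted p = 0.130 with an estimated correlation). Amino acid synthesis enzymes were likewise higher in 17 and lower in 1 of 20 cases (18 and 2 adjusted over the list alone). The median was 0.32 (camera adjusted p = 2.10e-06, adjusted p = 0.124 with an estimated correlation). Androgen-regulated genes were lower with the inhibitor in 15 and higher in 1 of 22 (the same adjusted over the list alone). Their median was −0.45 (camera adjusted p = 2.19e-05, adjusted p = 0.231 with an estimated correlation). Fatty acid synthesis genes were lower in 13 and higher in 2 of 15 (the same adjusted over the list alone). The median was −0.45 (camera adjusted p = 1.01e-05, adjusted p = 0.178 with an estimated correlation). In all 3699 genes were higher and 3729 lower with the inhibitor (51.9%). Across genes the fold changes of inhibitor and siPERK-1 had r = 0.148 (simulated 0.472, split controls −0.0128 to 0.101). Simulated r is shared noise and sets no standard. The covariance was 0.0158 against a simulated 0.0117. For siPERK-3 r was 0.118 (simulated 0.458, split controls −0.0285 to 0.0926), with a covariance of 0.0136 against 0.0118.

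**Figure D3:**
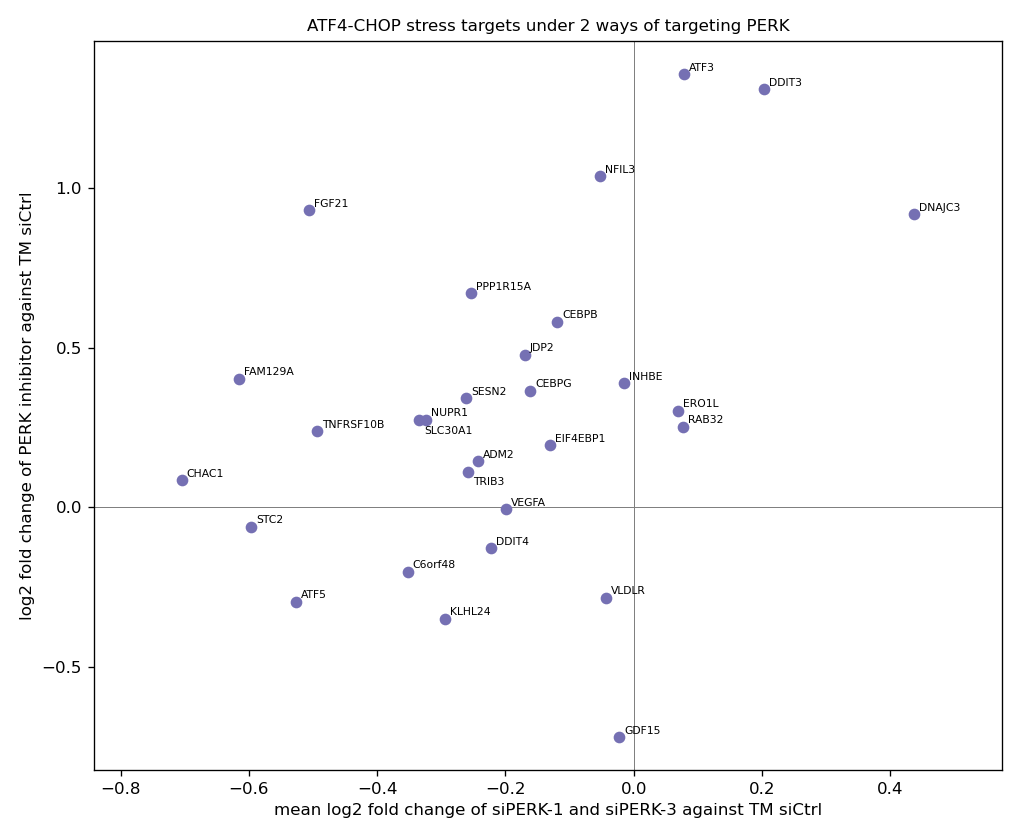
Log2 fold change of each tested ATF4-CHOP stress target with the PERK inhibitor (vertical axis) against the mean of siPERK-1 and siPERK-3 (horizontal axis), both against tunicamycin with control siRNA, 1 point per gene. DDIT3 (1.31) and ATF3 (1.36) lie highest on the inhibitor axis.

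The oligos of each target were compared as well. With siPERK-1 the synaptic vesicle gene SYP (1.39 ± 0.21), the aldo-keto reductase gene AKR1C2 (1.29 ± 0.21) and ZMYM6NB (1.26 ± 0.14) were higher than with siPERK-3. The endosome sorting gene BLOC1S6 (−1.34 ± 0.06), CD164 (−1.17 ± 0.06) and STMN4 (−0.99 ± 0.25, adjusted p = 0.0116, and −0.89 with adjusted p = 0.0548 without TM siPERK-1 replicate 3, within 0.00256 to 0.0548 over its alternatives) were lower. Cholesterol synthesis genes were lower with siPERK-1 than with siPERK-3 in 18 of 24 cases (20 adjusted over the list alone). Their median was −0.34 (camera adjusted p = 8.45e-25, adjusted p = 0.0337 with an estimated correlation). Heat shock genes were lower in 7 of 19 (12 adjusted over the list alone). The median was −0.21 (camera adjusted p = 2.40e-09, adjusted p = 0.124 with an estimated correlation). No ATF4-CHOP stress target was called by edgeR (0 of 29, and 0 adjusted over the list alone). The PERK oligos differed in 677 genes (321 higher and 356 lower with siPERK-1, or 47.4% higher, against 60.1% with upper-quartile factors). These counts of genes differing between the PERK siRNAs (TM siPERK-1 vs TM siPERK-3) depended on single libraries. Without TM siPERK-1 replicate 1, 224 were lower, without TM siPERK-1 replicate 3, 205 were higher and 211 lower, and without TM siPERK-3 replicate 1, 180 were higher and 212 lower.

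Between the ATF4 oligos 1221 genes were higher and 888 lower with siATF4-2. The named genes were COL16A1 (2.44 ± 0.44), CHAC1 (2.09 ± 0.51) and FAM129A (1.91 ± 0.22), which were higher, and PLCB1 (−1.68 ± 0.17), ACAP2 (−1.37 ± 0.10) and the RNA sensor gene DHX58 (−1.13 ± 0.23), which were lower. ATF4-CHOP stress targets were higher with siATF4-2 in 21 of 29 cases and lower in 1 (22 and 1 adjusted over the list alone). Their median was 0.56 (camera adjusted p = 9.30e-19, adjusted p = 0.0337 with an estimated correlation). Aminoacyl-tRNA synthetases were higher in 12 and lower in 2 of 20 (12 and 4 adjusted over the list alone; camera adjusted p = 1.99e-10, adjusted p = 0.0337 with an estimated correlation). Androgen-regulated genes were lower in 10 and higher in 1 of 22 (12 and 1 adjusted over the list alone). The median was −0.31 (camera adjusted p = 2.02e-08, adjusted p = 0.130 with an estimated correlation). The calls of COL16A1 (adjusted p = 0.000483, range over its alternatives 1.07e-08 to 0.0733) and CHAC1 (0.00698, and 0.102 as the highest of its alternatives) ended when only the compared groups were fitted, and without TM siATF4-2 replicate 4 CHAC1 differed by 1.45.

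Between ATF4 and PERK siRNAs 4528 genes were higher and 4624 lower with the ATF4 siRNAs (63.9%). ID1 (2.31 ± 0.20), the tyrosine kinase gene BMX (2.25 ± 0.19) and PKP1 (2.19 ± 0.16) were higher, and SERPINA3 (−4.93 ± 0.26, −5.61 without TM siATF4-3 replicate 1), LCN2 (−4.11 ± 0.22) and CHAC1 (−4.06 ± 0.24) lower. ATF4-CHOP stress targets were lower in 27 of 29 cases and higher in 2 (the same adjusted over the list alone). Their median was −1.24 (camera adjusted p = 1.45e-13, adjusted p = 0.0698 with an estimated correlation). Cholesterol synthesis genes were lower in 23 and higher in 1 of 24 (the same adjusted over the list alone). The median was −0.56 (camera adjusted p = 1.67e-10, adjusted p = 0.130 with an estimated correlation). Cell cycle genes were higher in 25 and lower in 1 of 32 (the same adjusted over the list alone). Their median was 0.41 (camera adjusted p = 1.01e-05, adjusted p = 0.130 with an estimated correlation).

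The 1215 genes raised at least 2-fold by tunicamycin were followed through the 5 treatments. Both ATF4 siRNAs lowered 952 of them (78.4%), both PERK siRNAs 406 (33.4%) and the inhibitor 113 (9.30%). The inhibitor raised 471 of them further, both PERK siRNAs 72 and both ATF4 siRNAs 16. TM siCtrl is the treated arm of one comparison and the control of the other, so chance differences in those libraries push the effects in opposite directions. Simulated unchanged groups gave 0 (again no test), and independent lists would give 296, 108 and 213. With a pair of TM siCtrl libraries for tunicamycin and the other pair for the treatments, 884 to 911 of 1249 to 1293 raised genes were lowered by both ATF4 siRNAs, 272 to 312 by both PERK siRNAs and 62 to 84 by the inhibitor. Across genes, the tunicamycin effect and that of siATF4-3 had r = −0.755 (simulated −0.0813, split controls −0.720 to −0.700, covariance −0.485 against a simulated −0.0116). Those of tunicamycin and siPERK-1 had r = −0.509 (simulated −0.0867, split controls −0.430 to −0.410, covariance −0.136 against −0.0119), and those of tunicamycin and the inhibitor had r = 0.201 (simulated −0.0835, split controls 0.189 to 0.235, covariance 0.0614 against −0.0118).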

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

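The tests of scaling, of the shared TM siCtrl libraries, of TM siATF4-2 replicate 4 and of a weaker inhibitor effect, the search for libraries that stand apart in single genes and the list tests between treatments were chosen only after the results they concern had been seen, and those of depth, uniform weakening, a larger effect of the same kind and other splits of the libraries before.

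ATF4-CHOP stress targets lay above TM siCtrl with the PERK inhibitor and below it with the PERK siRNAs (differences of 0.293 and −0.211 in the mean log2 CPM of the list). Scaling does not account for this, since the lowest inhibitor library lay at least 0.383 above the highest PERK siRNA library under 3 scalings, and depth does not, since the median log2 change between the treatments was 0.515 with every library thinned to 1 total and 0.526 before. As a weaker form of the siRNA effect the inhibitor could not raise the list. Its lowest library lay 0.248 above the highest TM siCtrl library. This argues against a weaker effect, with 15 of 29 members higher and 4 lower, but restates the pattern. Of the 6 members lower with both PERK siRNAs, 2 were higher with the inhibitor and 2 lower. The values are consistent with an inhibitor effect of another kind than that of the siRNAs, for which no cause was tested, and the list test between them did not hold with an estimated correlation (adjusted p = 0.130).

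Genes raised by tunicamycin were lowered by both ATF4 siRNAs, 952 of 1215. Shared TM siCtrl libraries do not account for this, since 884 of 1260 raised genes were lowered in the lowest of 6 divisions, with a pair of these libraries for tunicamycin and the other pair for both siRNAs, nor does scaling, with at least 963 under other factors. A uniform log2 weakening does not either (chi-square per gene around a single slope 32.3 with siATF4-2 and 51.6 with siATF4-3). Of the log2 rise in the 952 genes, a median of 55.1% (quartiles 35.9% and 80.4%) and 78.9% (51.5% and 106.9%) was removed. This may reflect a need for ATF4 that differs between genes. Other effects common to both oligos and a uniform loss in CPM were not tested.

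The ATF4 oligos differed in 2109 genes. Depth does not account for this (1980 genes with every library thinned to 1 total), and neither does TM siATF4-2 replicate 4, which kept more ATF4 (1638 genes without it). In 78.6% of the genes siATF4-3 went further in the direction of the siATF4-2 effect. This is in line with a larger effect of the same kind, as ATF4 stood at 114 CPM with siATF4-3 and 237 CPM with siATF4-2. The remaining genes may reflect effects of single oligos, which were not tested.

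In each comparison only the real split reached the real number of calls. Other splits mix groups, so this argues only weakly against chance. In fits of the compared groups alone and 35 splits, the real number and the highest of the other splits were 9652 and 0 for tunicamycin, 5155 and 1 for the inhibitor, 3723 and 1 for siPERK-1, 3799 and 2 for siPERK-3, 7461 and 0 for siATF4-2, 8738 and 0 for siATF4-3, 674 and 12 between the PERK siRNAs, and 1706 and 1 between the ATF4 siRNAs. In 100 drawn splits they were 7073 and 0 between inhibitor and PERK siRNAs and 8384 and 1 between ATF4 and PERK siRNAs.

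Differences between treatments were found by direct test. Between the PERK siRNAs 321 genes were higher and 356 lower with siPERK-1, with SYP (1.39), AKR1C2 (1.29), ZMYM6NB (1.26), BLOC1S6 (−1.34), CD164 (−1.17) and STMN4 (−0.99) in log2 units. Between the ATF4 siRNAs 1221 were higher and 888 lower with siATF4-2, with COL16A1 (2.44), CHAC1 (2.09), FAM129A (1.91), PLCB1 (−1.68), ACAP2 (−1.37) and DHX58 (−1.13). The inhibitor group had 3699 genes higher and 3729 lower than the PERK siRNA groups, with EIF2AK3 (2.44), PLCG2 (2.39), GCNT3 (2.32), OR51E1 (−2.76), UGT2B11 (−2.31) and TM4SF1 (−2.23). The ATF4 siRNA groups had 4528 higher and 4624 lower than the PERK siRNA groups, with ID1 (2.31), BMX (2.25), PKP1 (2.19), SERPINA3 (−4.93), LCN2 (−4.11) and CHAC1 (−4.06).

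Single libraries stood apart from the other 3 of their group in 21 of 237 group tests of library measures and named genes, where chance sets apart about 1 in 20. In TM siCtrl replicate 4 these were the share of the 10 most abundant genes (7.16%, lowest), MCM2 (21.4 CPM), MCM5 (14.6 CPM), TARP (6.11 CPM) and HOPX (13.4 CPM, lowest). In TM siATF4-2 replicate 4 they were LCN2 (3.52 CPM), CHAC1 (21 CPM), FLRT1 (2.08 CPM), SERPINA3 (2.16 CPM) and SEMA6A (48.4 CPM, lowest), and in TM siATF4-3 replicate 4 CHAC1 (4.29 CPM), FIBIN (0.729 CPM) and ACAP2 (80.9 CPM, lowest). The inhibitor group had PLCG2 in replicate 3 (37.5 CPM) and COLCA1 in replicate 4 (29.9 CPM), and TM siPERK-3 had DMGDH in replicate 2 (4.17 CPM), TM4SF1 in replicate 3 (8.37 CPM, lowest) and TMEM165 (34.6 CPM) and BMX (1.63 CPM) in replicate 4. The remaining ones were LAMP3 in DMSO siCtrl replicate 4 (0.211 CPM, lowest) and BMX in TM siATF4-3 replicate 3 (6.64 CPM).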

How the results depend on the processing

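None of the alternatives below, pairs of TM siCtrl libraries included, was chosen after the results were seen. Only the explanation tested with those pairs was. DESeq2, DESeq2 size factors, limma-voom, upper-quartile factors, no low-count filter, a stricter filter and a fit of only the compared groups each left all 39 counts of genes within 1.5 times their value and reversed no direction. With the replicate number as a block, 550 genes were higher and 645 lower with siPERK-1 than with siPERK-3 (321 and 356 without it), and the other 37 counts stayed within 1.5 times. The block ended none of 619 calls of named genes and gave 3 more: FAM129A with the inhibitor (adjusted p = 0.0409), ATF4 with siPERK-3 (0.0344) and EIF2AK3 with siATF4-3 (0.0197). Of the list calls it ended NF-kB targets with siATF4-2 (adjusted p = 0.0501) and gave p53 targets with tunicamycin (0.0433) and fibroblast markers with siPERK-1 (0.0401). All 28 libraries were closest to their own number (mean r 0.102, other numbers −0.0338). This points to shared experiments, which the main fit left out. In none of 8 group pairs did every r pass 0.1, but each was positive (lowest 0.0316). A minimum change of 2-fold, which by construction asks more of each gene, left 1215 genes higher and 1041 lower with tunicamycin, 114 and 111 with the inhibitor, 99 and 71 with siPERK-1, 101 and 123 with siPERK-3, 235 and 642 with siATF4-2 and 403 and 947 with siATF4-3.

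With the TM siCtrl libraries divided into 2 pairs, fewer libraries were compared. With a pair for each oligo both PERK siRNAs raised 666, 606, 636, 652, 619 and 647 genes and lowered 758, 725, 755, 720, 727 and 740 in the 6 splits. With a pair for tunicamycin and the other for the inhibitor, 71, 74 and 62 of the tunicamycin-raised genes were lowered by the inhibitor in 3 of them. Without single libraries the genes between the PERK siRNAs ranged from 180 to 286 higher and 211 to 341 lower, for which the cause was not tested beyond the smaller number of libraries, and 367 of 372 such counts stayed within 1.5 times. Of 624 values for named genes 619 were called. DESeq2 ended 7 of these calls, DESeq2 size factors 1, limma-voom 1, upper-quartile factors 4, no filter 10 and a fit of only the compared groups 11, and a stricter filter none. Of the 5 values not called, limma-voom called 2, upper-quartile factors 1 and a fit of only the compared groups 4. Leaving out single libraries ended 151 calls, kept 4873 and gave 1. For the lists, an estimated correlation ended 78 of 88 calls, upper-quartile factors ended 0 and gave 3 more, DESeq2 size factors changed none and fry, which asks another question, called all 88 and 26 more. Leaving out single libraries ended 12 list calls, kept 692 and gave 9. Depth limits genes with few counts: with every library thinned to 1 total 13867 genes were tested instead of 14314, and 1980 instead of 2109 differed between the ATF4 siRNAs.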

Other observations

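The genes and overlaps here were chosen after their values were seen. Among the genes lowered by the inhibitor and by both PERK siRNAs (values in that order, in log2 units) were the Golgi gene TMEM165 (−1.48 ± 0.13, −1.52 ± 0.13 and −1.43 ± 0.13), the membrane gene TMEM9B (−1.12 ± 0.08, −0.98 ± 0.08 and −1.01 ± 0.08), the trans-Golgi gene TGOLN2 (−1.18 ± 0.07, −0.97 ± 0.07 and −1.01 ± 0.07), the lysosomal protease gene CTSO (−1.45 ± 0.16, −1.32 ± 0.16 and −1.08 ± 0.16) and FITM2 of lipid droplet formation (−1.52 ± 0.16, −1.09 ± 0.15 and −0.99 ± 0.15). In all 336 genes were lower in the 3 comparisons and 332 higher (independent lists 222 and 213). With a TM siCtrl pair for the inhibitor and the other for both siRNAs the counts were 195 to 212 and 182 to 201 (independent 86.2 to 145 and 75.4 to 131). The inhibitor raised 320 genes both PERK siRNAs lowered and lowered 242 they raised. Here chance overlap was not computed, so same-way excess does not show a shared effect. Both ATF4 siRNAs lowered 221 of the 336, not the genes named above, and raised 29. They raised 165 of the 332 and lowered 47 (chance not computed), among the latter AGT (1.87 ± 0.32, 1.67 ± 0.32 and 1.17 ± 0.34, against −2.56 ± 0.58 and −3.35 ± 0.68 with them).

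TMEFF2, ACPP, RLN1 and OR51E1 were lowered by tunicamycin and raised by both PERK siRNAs, while the list of androgen-regulated genes was not called with either (camera adjusted p = 0.396 and 0.738). TMEFF2 went from 166.6 ± 20.4 CPM in DMSO siCtrl to 21.7 ± 10.1 CPM in TM siCtrl, and stood at 20.1 ± 9.27 CPM with the inhibitor (adjusted p = 0.826), 80.2 ± 16.2 and 92.9 ± 16.7 CPM with the PERK siRNAs and 102.5 ± 5.74 and 152.0 ± 6.53 CPM with the ATF4 siRNAs. ACPP changed by −1.55 ± 0.29 with tunicamycin and by 2.09 ± 0.29 and 1.76 ± 0.30 with the PERK siRNAs, RLN1 by −2.95 ± 0.30, 2.19 ± 0.33 and 2.02 ± 0.35, and OR51E1 by −3.96 ± 0.26, 2.47 ± 0.31 and 1.86 ± 0.34.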
